A study of Mus musculus with 22 samples.

How the data were processed

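H3K4me3 was measured by ChIP-seq in mouse synovial fibroblasts of a mixed CBA and C57BL/6J background. There were 21 libraries in 7 groups of 3, which were Tg197 and wild-type (WT) cells at 3, 8 and 11 weeks of age and WT cells of 8 weeks treated with TNF, and 1 input library. Groups were taken from the labels. Whether the 3 libraries of a group came from separate animals or from separate cultures is not given in the sources used here, so the tests measure the spread between these libraries only.

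The data were 4 deposited tables, one for each of Tg197 against WT at 3, 8 and 11 weeks and TNF-treated against untreated WT cells at 8 weeks. Each table listed regions on the mm9 build that had a best window with p of at most 0.0001 in the authors' comparison, so regions without a difference were not part of the data. The submitters' processing notes list mm9, BWA, TopHat, Cufflinks, TopHat2 and Cuffdiff without versions and without saying which of them served the H3K4me3 data. The region caller is not given in the sources used here.

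Per the file headers, each region carried 3 normalized counts for the treated and 3 for the control group, made by the authors and held together in 1 cell per group. The deposited group averages are the signal, and each equals the mean of those 3 values. The authors' enrichment columns hold a ratio over an input, scaled in a way not given in the sources used here. The authors' fold columns are on the log2 scale, as treated over control. The deposited p-value columns hold the p of the authors' test and its adjusted p-value, for the region and for its best window. Positions of regions relative to the nearest transcription start site (TSS) were taken from the deposited annotation, where promoter classes reach 250 bp, 1 kb or 3 kb from the TSS. Here, promoter means any of these 3 classes.

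The 3 values in a cell carry no replicate number, so the libraries are called a, b and c by their place in the cell, and no library was matched to a numbered replicate. Every value was a whole multiple of 1 step per library within a tolerance of 0.02 normalized reads, in 100.0% of values, so whole reads per library were recovered and their sums give the depth. The headers say only treatment and control. Control was read as WT because the control libraries of both 8 week tables held equal reads in all 162 values of the 54 regions with identical coordinates, and WT at 8 weeks is the only group tied by the labels to both tables. The 3 and 11 week tables were read the same way.

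The tables differed from both forms that had been foreseen, counts for every sample or the authors' comparison alone, since they held normalized counts for each library together with that comparison. The number of changed regions is therefore the number past the authors' adjusted p of 0.05, and regions past it are called higher or lower. As a test on the libraries themselves, limma 3.58.1 in R 4.3.3 was run on log2 of the normalized count plus 0.5 with a trend in the variance, and rose and fell are used for regions past its Benjamini-Hochberg adjusted p of 0.05. The deposited values are normalized, so limma was run on their logarithm, and of the methods for counts only voom was run, on the recovered reads. The listed regions had been selected on the same libraries, so limma's adjusted p covers the listed regions only and is not independent evidence that they differ. Data were simulated with the depths of each table, 1 average spread for all its regions and libraries, and 100 regions changed by each fold. The same limma test recovered 38% and 93% of regions changed 1.5-fold and 2-fold at 3 weeks and 6% and 32% at 8 weeks. It recovered 86% and 100% at 11 weeks, and 23% and 89% in the TNF table. False calls made up 8.4%, 2.6%, 5.1% and 3.4% of the calls in those simulated tables. The simulated noise was independent between regions and few regions changed, unlike the real tables, so these rates do not carry over to them. At 8 weeks 1244 regions past the authors' adjusted p had an absolute log2 change of at least 1, and limma called 0.

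Shares of regions have exact Clopper-Pearson 95% intervals, which cover counting error only, since neighbouring regions are not independent. Position was compared between higher and lower regions with a two-sided Fisher's exact test. That test counts regions of the same libraries as independent, so its p does not measure the spread between libraries. The 16 gene lists include 5 of markers of other cell types that a fibroblast culture could hold. For each list and comparison, members with only higher or only lower promoter regions were set against all other genes of the same table (57 tests), and presence among genes with a higher, or a lower, promoter region was set against 21900 protein-coding genes (64 tests in each direction), both with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment. The 21900 genes were not limited to genes with H3K4me3 in these cells. Places with too few reads to show a difference could not be listed. A presence test can thus pass for a list of marked genes without a change particular to that list. Of 7858 gene symbols in the tables, 7823 matched the gene table by symbol or synonym. For list members, limma calls are given over all regions and adjusted over the list alone, and count every member with a listed promoter region, past the authors' adjusted p or not. Overlaps of regions needed 1 shared base (bedtools 2.31.1) and were set against 1000 circular shifts along each chromosome and against the share of same-direction pairs that the directions in both tables give. Shifts could place a region anywhere on its chromosome, and numbers from independent lists drew on all protein-coding genes. Whether a region had to hold a peak to be listed is not given in the sources used here. Places with too few reads to show a difference could not be listed, so both expected numbers are low. An excess over them is not by itself a shared response. The expected share of same-direction pairs takes no account of position relative to a TSS, which went with direction in every table. Overlapping regions share their position, so an excess over that share is not by itself a shared response either. The comparisons, thresholds, gene lists, the rule for naming genes and, unless stated, the tests other than limma were fixed before the data were examined. Limma was not among the planned tests and was added once the form of the deposited data was known. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

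Named genes followed a rule. Among promoter regions past the authors' adjusted p with a mean of at least 20 normalized reads in the higher group, and leaving out clone-type symbols, it took the 6 genes with the largest fold in each direction (ties by p) and the 3 with the smallest p in each direction not yet named (ties by fold). It also took up to 4 members of each list with the smallest adjusted p in regions of any class, Tnf wherever it had a region, and up to 10 genes with a promoter region changed the same way at all 3 ages, by their largest p. Every other gene named in the text, such as further list members, genes shared by all 4 comparisons and the genes under other observations, was chosen after its values were seen.

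Alternatives tried were other thresholds of adjusted p and fold, every listed region, a minimum of 20 normalized reads, promoter regions only, merged neighbouring regions, autosomes only, other overlap rules and leaving out each library in turn. Chosen after seeing the data were voom on the recovered reads, a pseudocount of 5, scaling each library to its median over the listed regions or over listed regions within 1 kb of a TSS, and the overlaps of the 3 and 11 week tables with the TNF table. The input library has no values of its own in the tables and was not analysed here.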

Results

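H3K4me3, a histone mark found at active promoters, was profiled in synovial fibroblasts, the stromal cells of the joint lining. The cells came from Tg197 mice, which carry a human TNF transgene and develop arthritis, and from WT mice, at 3, 8 and 11 weeks, ages that the series design calls early, established and late. A further group held WT cells of 8 weeks treated with TNF. Each group had 3 libraries. Values are the authors' normalized read counts in a region, given as mean ± SD with n = 3 per group unless stated, and log2 changes carry the standard error from limma. The listed regions held between 1560963 and 2780941 reads per library at 3 weeks, between 390496 and 849692 at 8 weeks, between 807633 and 1096917 at 11 weeks and between 321448 and 1312112 in the TNF table. Depth relative to the authors' scaling ran from 0.5438 to 2.753, both in the TNF table. All replicate pairs differed by more than counting noise, with a mean chi-square per region from 1.3 to 65.81.

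Only regions with a difference were listed, so the authors' scaling could not be checked on unchanged regions. The median limma change over the listed regions was -0.70 at 3 weeks, -0.86 at 8 weeks, -0.60 at 11 weeks and -0.58 with TNF. With each library scaled to its median over the listed regions, a choice made after seeing the data, the same medians were -0.04, -0.15, -0.26 and -0.07. With scaling to listed regions within 1 kb of a TSS they were -1.04, -0.99, -0.75 and -0.69. The first of these moves the balance toward higher regions by construction, since most listed regions were lower, and the second moves promoters down by construction, since more of the regions near a TSS were higher than lower, so neither shows which directions are right. Directions below are those of the authors' scaling, and places where a list or a count turns under another scaling are given with it.

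**Figure D1:**
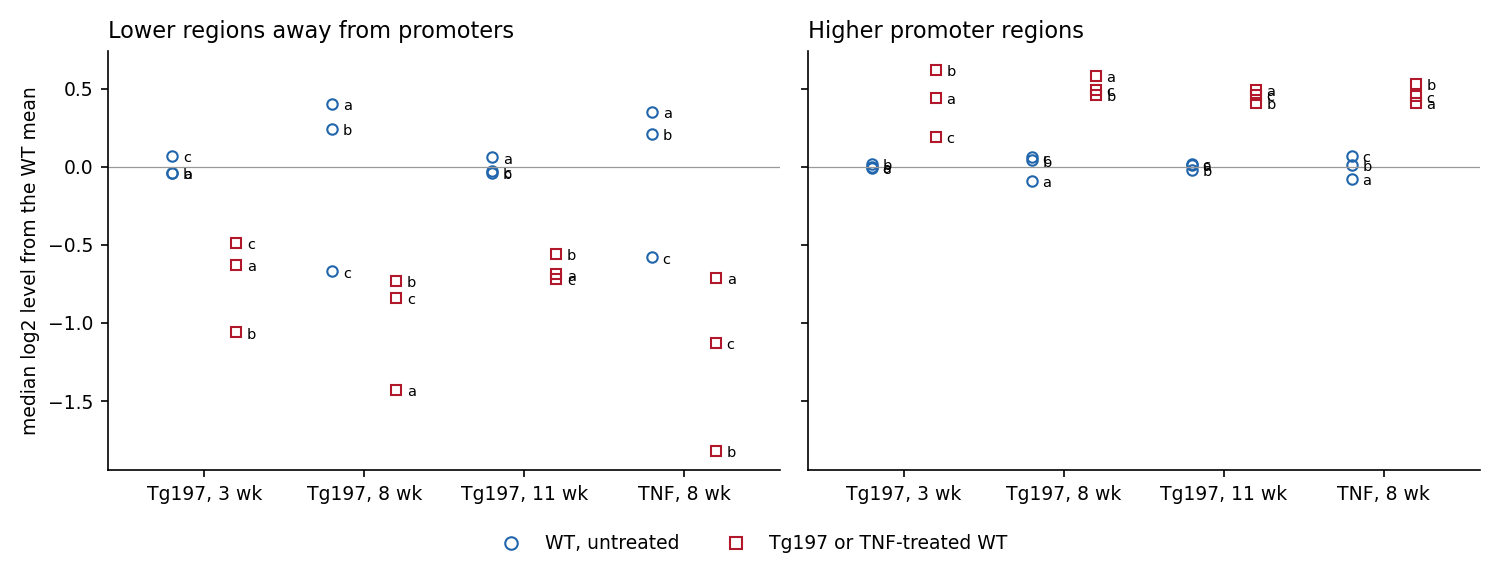
Median log2 level of each library from the WT mean (y axis) in the 4 comparisons (x axis), over lower regions away from promoters (left) and higher promoter regions (right). Each point is 1 library with its letter, circles are untreated WT and squares Tg197 or TNF-treated WT. At lower regions the 8 week WT library c lies at -0.67 beside 0.40 and 0.24 for the other WT libraries under the authors' scaling, and these levels shift with the scaling.

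The 3 week comparison addressed the early stage of disease. Promoters of NF-kB feedback genes carried more H3K4me3 in Tg197 cells. Tnfaip3, which encodes the deubiquitinase A20 that limits NF-kB signalling, had 601.2 ± 147.8 normalized reads against 311.4 ± 54.6 in WT (chromosome 10, 18732601 to 18735000), a 1.93-fold difference and the largest among named promoters (log2 change 0.93 ± 0.22, limma adjusted p = 0.0143). Nfkbia, which encodes the NF-kB inhibitor IkB-alpha, had 1057.1 ± 218.5 against 615.0 ± 107.2 (chromosome 12, 56590601 to 56594400), a 1.72-fold rise. Ch25h, an enzyme that makes 25-hydroxycholesterol, rose 1.81-fold, Tank, an adaptor of TRAF signalling, rose 1.72-fold, and Sox11, a developmental transcription factor, rose 1.84-fold. In the other direction, Hsh2d, a haematopoietic adaptor protein, fell from 137.1 ± 26.3 to 52.2 ± 8.1 (log2 change -1.38 ± 0.26), and regions near the apolipoprotein genes Apoa1 (-1.31 ± 0.35) and Apoc4 (-1.24 ± 0.33) and near Rnf43, a Wnt receptor ligase (-1.32 ± 0.36), fell as well. Miat and Zfp74 also fell with a log2 change of -1.38 each, and Stau2 rose 1.71-fold.

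Of the 29 members of the list of NF-kB targets and regulators, 11 had higher and 2 had lower promoter regions at 3 weeks, and the other members had none past the threshold. Higher were Birc2, Icam1, Nfkb2, Nfkbia, Nfkbie, Nfkbiz, Sod2, Tnfaip3, Tnfrsf1b, Tnip1 and Vcam1, and lower were Rela, an NF-kB subunit (-0.60 ± 0.17), and Tnfaip2. The promoter of Tnip1, a partner of A20, rose from 347.8 ± 43.5 to 558.2 ± 65.8, that of Nfkb2 1.41-fold and that of Vcam1, an adhesion molecule for leukocytes, 1.38-fold. The list's members were over-represented among genes with a higher promoter region (adjusted Fisher's exact p = 7.3e-07), while its balance of higher and lower members against other genes did not pass (adjusted Fisher's exact p = 0.0511). That balance passed at an authors' adjusted p under 0.001 (adjusted Fisher's exact p = 0.0257). The presence test was against all protein-coding genes, with or without the mark, so alone it does not show a change particular to the list. In limma 11 members passed over all regions and 11 adjusted over the list alone, and the list's median log2 change of 0.47 was 1.14 and 0.14 under the other scalings.

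In the extracellular matrix list 2 members were higher (Fbln2 and Vcan) and 8 lower (Col1a1, Col6a1, Col6a2, Fbn1, Fmod, Fn1, Lox and Lum), with 10 past limma over all regions and 10 adjusted over the list alone. Fmod, a collagen-binding proteoglycan, fell from 247.9 ± 14.9 to 154.0 ± 10.3, and Fn1, which encodes fibronectin, fell by 0.69 on the log2 scale. The list did not pass as over-represented among lower genes (adjusted Fisher's exact p = 0.0904), and its median log2 change of -0.59 turned to 0.08 with scaling to the listed regions. In the bone and Wnt/BMP list 2 members were higher (Chrd and Spp1) and 6 lower (Axin2, Bmp4, Dkk3, Nog, Sfrp1 and Sp7), with all 9 members that had a listed promoter region past limma both over all regions and adjusted over the list alone, 1 of them not past the authors' adjusted p, and a median of -0.55 that turned to 0.12 with scaling to the listed regions. Bmp4, a bone morphogenetic protein, fell from 367.2 ± 71.5 to 195.9 ± 45.9. Antigen presentation genes H2-D1, H2-K1, H2-T23 and Tapbp were higher and H2-DMa lower (3 past limma over all regions and 3 adjusted over the list alone), and that list's median log2 change of 0.28 turned to -0.05 with scaling to regions within 1 kb of a TSS. Among interferon response genes Irf1, a transcription factor that NF-kB also induces (1.68-fold), and Xaf1 (1.63-fold) rose, and Ifi35 and Isg20 fell. The Tnf gene itself had a lower gene-body region, with 91.0 ± 16.8 against 136.1 ± 12.7 (chromosome 17, 35335001 to 35336200), a log2 change of -0.59 ± 0.20 that is smaller than the shift between scalings.

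The remaining lists at 3 weeks had members in both directions or 1 or 2 members. Among proteases and inhibitors Adamts2, Adamts4 and Adamts5 were higher, and Ctsk and Mmp11 were among the lower members. Cytoskeleton and adhesion had 4 higher (Actn1, Tagln, Vim and Zyx), 4 lower (Cdc42, Itga1, Itga11 and Myl9) and Lpp in both directions. Homeobox and limb patterning had 4 higher (Emx2, Meis2, Shox2 and Twist2) and 4 lower (Hoxa13, Hoxc4, Hoxc9 and Tbx18). Cell cycle had 2 higher (Cdk6 and Cdkn1a), 4 lower (Aurkb, Cdk4, Mcm6 and Pcna) and Ccnd1, which encodes cyclin D1, in both. Median log2 changes that turned with scaling to the listed regions were those of cell cycle (-0.53 to 0.14) and homeobox genes (-0.09 to 0.57) and of endothelial (-0.03 to 0.64) and cartilage, bone and fat markers (-0.50 to 0.16), and those of interferon response (0.10 to -0.23), cytoskeleton (0.06 to -0.27) and protease genes turned with scaling to regions within 1 kb of a TSS. Chemokines and cytokines had only Lif, which was lower. Synovial fibroblast markers had 3 higher (Pdgfrb, Pdpn and Vcam1) and 1 lower (Col6a1). Among markers of other cell types Itgam (leukocytes), Tek (endothelium), Ckm (muscle), Comp (cartilage) and Cdh1 (epithelium) were lower, the direction of most listed regions, and Flt1 (endothelium) was higher.

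At 3 weeks 13494 regions in all passed the authors' adjusted p, 1321 higher and 12173 lower in Tg197 (9.8% higher, 95% interval 9.3 to 10.3). Of the higher regions 90.3% lay within 3 kb of a TSS, and of the lower regions 14.5% did (odds ratio 55.0 by Fisher's exact test). The lower regions were mostly in gene bodies (6256) and intergenic sequence (4006), and their median log2 change was -0.70 against 0.43 for higher regions. By limma 637 regions rose and 12096 fell. The counts were 940 and 6 with scaling to the listed regions and 3 and 12238 with scaling to regions within 1 kb of a TSS. Without WT library c limma called 0 regions (9776 at an unadjusted p under 0.05), without WT library a 8117 and without WT library b 7955, and voom called 12774 with all 6 libraries.

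**Figure D2:**
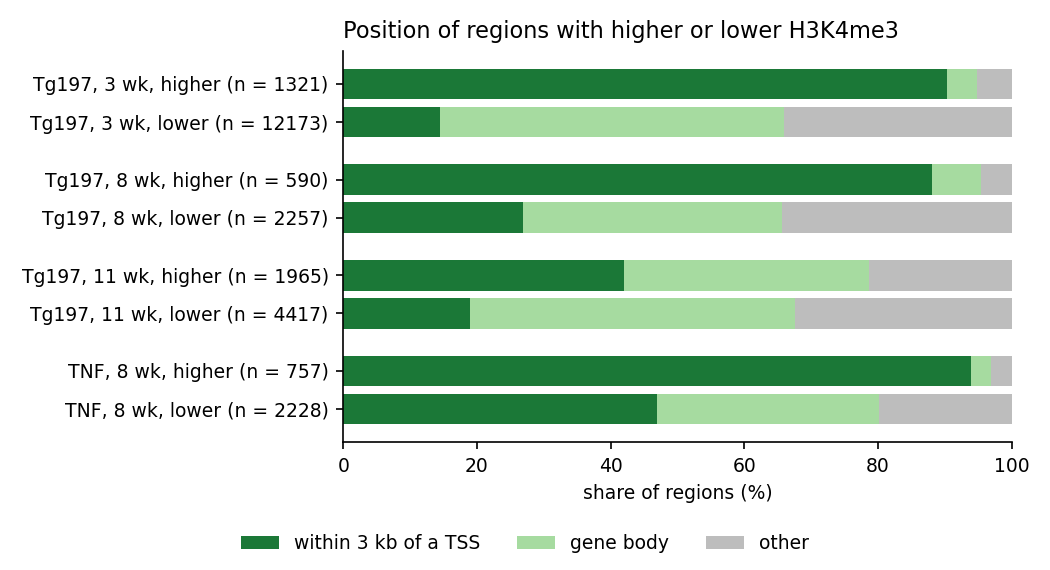
Share of regions (x axis, percent) within 3 kb of a TSS, in gene bodies or elsewhere, for regions higher or lower than in the control group in each of the 4 comparisons (y axis, with the number of regions). Higher regions lay within 3 kb of a TSS in 90.3%, 88.1%, 42.0% and 93.9% of cases from top to bottom, and lower regions in 14.5%, 26.9%, 18.9% and 46.9%, with directions as in the authors' scaling, and the balance of higher and lower turns by construction when libraries are scaled to the listed regions, which are mostly lower.

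At 8 weeks, the age of established disease, the same feedback genes had higher promoter H3K4me3 in Tg197 cells, though no region passed limma. Nfkbia had 500.3 ± 74.2 against 284.7 ± 17.1 normalized reads (1.76-fold, log2 change 0.80 ± 0.20, limma adjusted p = 0.0725), Tnip1 had 195.8 ± 64.4 against 108.6 ± 24.4 (1.8-fold) and Tnfaip3 had 437.1 ± 98.0 against 273.5 ± 9.0 (1.6-fold). Thy1, a surface marker of sublining fibroblasts, had 318.5 ± 8.9 against 199.1 ± 13.2 (1.6-fold), and Pdpn, a marker of activated synovial fibroblasts, was 1.53-fold higher. Ddx60, an interferon-induced helicase, was 1.73-fold higher, and Csnk1g3 1.81-fold. The largest fold among named promoters with higher levels, 1.85 at Mndal, came with overlapping groups (139.9 ± 81.8 against 75.6 ± 9.4). Lower were Sp7, which encodes the osteoblast factor osterix (85.9 ± 28.3 against 172.0 ± 14.4, log2 change -1.06 ± 0.31), Edar, the ectodysplasin receptor (-1.45 ± 0.35), Nol3, an inhibitor of apoptosis (-1.46 ± 0.47), and Cml3 (-1.60 ± 0.60). Speer4e, Tdpoz3 and Tdpoz4, which were also among the largest decreases at named promoters, belong to families of near-identical gene copies and had overlapping groups.

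Of the NF-kB list 4 members were higher (Nfkbia, Nfkbie, Tnfaip3 and Tnip1) and 0 lower, over-represented among higher genes (adjusted Fisher's exact p = 0.0287), while the direction test did not pass (adjusted Fisher's exact p = 0.524). Limma passed 0 of them over all regions and 3 adjusted over the list alone, and the median log2 change of 0.73 was 1.44 and 0.60 under the other scalings. The cytoskeleton and adhesion list was also over-represented among higher genes (adjusted Fisher's exact p = 0.00937), with 5 members higher and Vcl lower, while its direction test did not pass (adjusted Fisher's exact p = 0.7). The higher ones were Acta2, the smooth muscle actin of myofibroblasts (562.1 ± 63.0 against 341.7 ± 53.7), the hyaluronan receptor Cd44 (1.36-fold), and the contractility regulators Rhoa, Rock1 and Rock2. In that list 0 passed limma over all regions and 2 adjusted over the list alone. As at 3 weeks, the presence tests were against genes with or without the mark. Lower without any higher member were the homeobox list (Hoxa13, Hoxa5, Hoxc6, Hoxd9 and Irx3) and the bone and Wnt/BMP list (Runx2, Sfrp1 and Sp7), and the homeobox list's median log2 change of -0.67 turned to 0.04 with scaling to the listed regions. Neither was over-represented among lower genes (adjusted Fisher's exact p = 0.13 and 0.314). In limma 0 members of either list passed over all regions, and 0 homeobox and 2 bone and Wnt/BMP members adjusted over the list alone.

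In the other lists at 8 weeks, cell cycle had Cdc20, Cdk4 and Top2a lower and Ccnd1 in both directions. Synovial fibroblast markers had Pdpn and Thy1 higher and Htra4 lower (0 past limma over all regions and 3 adjusted over the list alone). Among proteases and inhibitors Timp3 was higher. Each remaining list of processes had 1 member, lower in each case, namely Csf1 (chemokines and cytokines), Ifit3 (interferon response), H2-DMa (antigen presentation) and Fbln1 (extracellular matrix). Medians turned with scaling to the listed regions for chemokines and cytokines (-0.46 to 0.25), interferon response (-0.12 to 0.59), cartilage, bone and fat markers (-0.62 to 0.09) and proteases. Cd79a and Fcer1g (leukocytes), Ckm (muscle) and Comp and Sox9 (cartilage) were lower, and endothelial markers and nerve sheath and epithelial markers had no member.

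The table had 2847 regions past the authors' adjusted p, 590 higher and 2257 lower (20.7% higher, 95% interval 19.2 to 22.3). Higher regions lay within 3 kb of a TSS in 88.1% of cases and lower ones in 26.9% (odds ratio 20.2, Fisher's exact p = 6.41e-168). Here and in the later comparisons, the p for position counts regions as independent and does not measure the spread between libraries. Limma called 0 regions, with 1876 at an unadjusted p under 0.05, and voom also called 0. Without WT library c, which lay near the Tg197 libraries at lower regions, limma called 2563 regions, 328 that rose and 2235 that fell. With scaling to the listed regions limma called 414, of which 338 rose and 76 fell, and with scaling to regions within 1 kb of a TSS 1730, of which 12 rose and 1718 fell.

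At 11 weeks, the late stage, promoters with more H3K4me3 in Tg197 cells included those of NF-kB genes and of 4 chemokine genes. Chl1, a neural cell adhesion molecule, had the largest rise among named promoters, from 94.9 ± 18.5 to 222.6 ± 43.4 normalized reads (2.35-fold, log2 change 1.23 ± 0.17, limma adjusted p = 0.00362). Tnip1 rose from 295.5 ± 46.2 to 584.7 ± 87.8 (1.98-fold), Nfkbia from 374.0 ± 6.1 to 705.8 ± 125.8 (1.89-fold) and Tnfaip3 from 454.4 ± 19.6 to 752.8 ± 116.6 (1.66-fold). Ccl2, a chemokine that attracts monocytes, rose from 219.9 ± 21.6 to 376.6 ± 34.5 (chromosome 11, 81848401 to 81851300) and Cxcl1, which attracts neutrophils, 1.61-fold. Dram1, a regulator of autophagy, rose 1.99-fold, Slit1, an axon guidance ligand, 1.98-fold and the neuropeptide Y receptor gene Npy1r 1.97-fold. Sigirr, an inhibitor of interleukin-1 and Toll-like receptor signalling, fell from 132.0 ± 24.3 to 62.1 ± 5.8 (log2 change -1.07 ± 0.19), and Wnt10a (-1.05 ± 0.26), Bmp4 (-0.85 ± 0.13) and Sp7 (-0.68 ± 0.14) fell too.

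The NF-kB list had 10 members higher and 0 lower (Birc3, Icam1, Nfkb1, Nfkbia, Nfkbie, Ripk2, Tnfaip2, Tnfaip3, Tnip1 and Vcam1), and it passed both the direction test (adjusted Fisher's exact p = 0.0256) and the presence test (adjusted Fisher's exact p = 3.32e-07). All 10 rose by limma, over all regions and adjusted over the list alone. The list's median log2 change of 0.72 was 1.06 and 0.57 under the other scalings. Random lists of listed promoters of similar level had a median of 0.31, and the presence test was against genes with or without the mark. The apoptosis inhibitor gene Birc3 rose from 131.8 ± 17.9 to 218.7 ± 7.7 and the adhesion molecule gene Icam1 from 276.6 ± 15.3 to 458.1 ± 54.6. The direction test did not pass at an authors' adjusted p of 0.001 (0.0603 by Fisher's exact test, adjusted) or over every listed region (0.0534). Chemokines and cytokines had 4 members higher (Ccl2, Ccl7, Cxcl1 and Cxcl12) and 0 lower at promoters, and passed neither the direction test (adjusted Fisher's exact p = 0.524) nor the presence test (adjusted Fisher's exact p = 0.0776). With regions of any class 6 members were higher and 0 lower, and the direction test passed (adjusted Fisher's exact p = 0.0367). Of the 4 with promoter regions, 3 rose by limma over all regions and 3 adjusted over the list alone, and Cxcl12 had 415.7 ± 97.3 against 330.3 ± 12.2.

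Interferon response genes Bst2, Ifit2, Irf1, Mx2 and Oasl2 were higher and Oasl1 lower at 11 weeks, all 6 past limma over all regions and adjusted over the list alone. Ifit2 rose 1.57-fold and Bst2, which encodes tetherin, 1.47-fold. Synovial fibroblast markers Col6a1, Pdgfra, Pdgfrb and Vcam1 all rose by limma (4 over all regions and 4 adjusted over the list alone), and the list was over-represented among higher genes (adjusted Fisher's exact p = 0.0213), while its direction test did not pass (adjusted Fisher's exact p = 0.524). A background of all protein-coding genes, with or without the mark, favours a list of fibroblast markers in the presence test. The median log2 change of these 4 markers was 0.42, and 0.76 and 0.27 under the other scalings. Antigen presentation had B2m, H2-Ab1 and H2-K1 higher, of which 2 passed limma over all regions and 2 adjusted over the list alone.

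Bone and Wnt/BMP signalling had Dkk2 and Wnt9a higher and Axin2, Bmp4, Fzd4, Sp7 and Wnt5b lower, 7 past limma over all regions and 7 adjusted over the list alone, with a median log2 change of -0.68 that stayed negative under both other scalings (-0.34 and -0.83). Extracellular matrix had Col6a1 and Loxl1 higher and Col12a1, Col6a2, Fn1 and Sparc lower. Proteases and inhibitors had Adam12 and Adamts5 higher and Plau lower, and cell cycle had Ccnd1, Cdkn1a and Trp53 higher and Aurkb and Cdk2 lower. Cytoskeleton and adhesion had Pxn, Rac1 and Tpm1 higher, Itga1, Myl9 and Rhoa lower and Myh9 in both directions, and the homeobox list had En1 higher and Hoxa10, Hoxa13, Irx3 and Irx5 lower. With scaling to the listed regions the medians of the homeobox list (-0.29 to 0.05) and of endothelial markers (-0.08 to 0.26) turned, that of extracellular matrix went from -0.34 to 0.00, and that of cytoskeleton, 0.00, went to 0.34. Coro1a (leukocytes), Tek (endothelium), and Adipoq, Cebpa and Comp (fat and cartilage) were lower, while Pecam1 (endothelium) and the nerve sheath markers Ngfr and Sox10 were higher. Muscle markers had no member.

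The table had 6382 regions past the authors' adjusted p, 1965 higher and 4417 lower (30.8% higher, 95% interval 29.7 to 31.9). Higher regions lay within 3 kb of a TSS in 42.0% of cases and lower ones in 18.9% (odds ratio 3.1, Fisher's exact p = 5.9e-80), and 720 of the higher regions were in gene bodies and 409 in intergenic sequence. By limma 1952 regions rose and 4462 fell. The counts were 2078 and 681 with scaling to the listed regions and 1486 and 4519 with scaling to regions within 1 kb of a TSS.

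**Figure D3:**
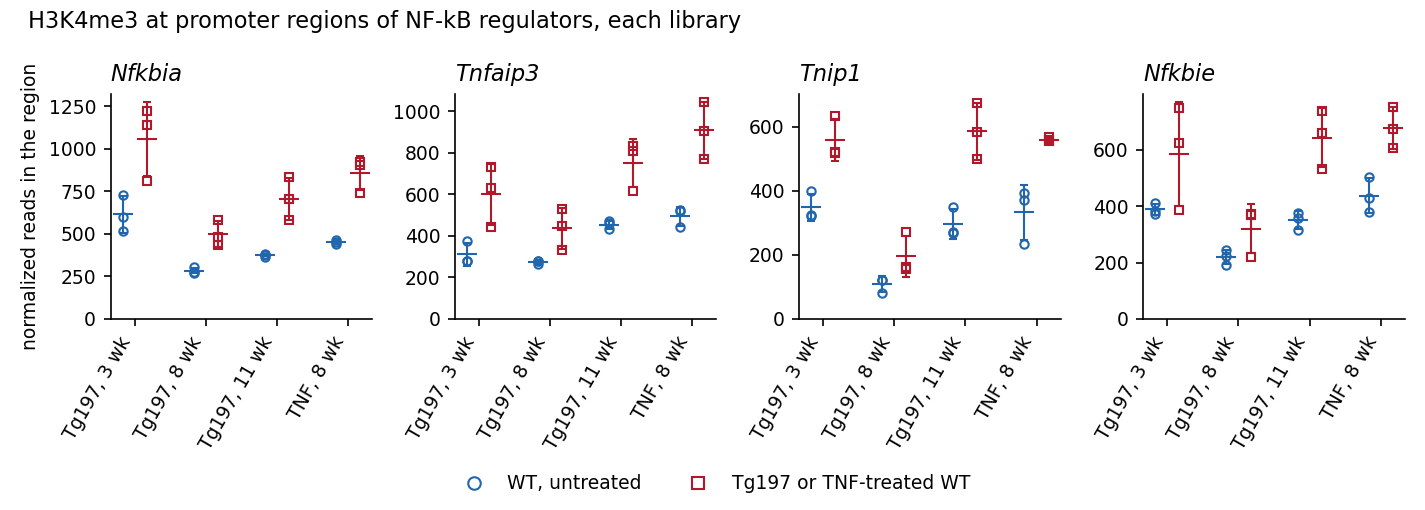
Normalized reads (y axis) at promoter regions of Nfkbia, Tnfaip3, Tnip1 and Nfkbie in each comparison (x axis). Each open symbol is 1 library, horizontal bars are means and error bars SD (n = 3), with WT as circles and Tg197 or TNF-treated WT as squares, and values are to be compared only within a comparison. The genes were chosen from those with a higher promoter region in every comparison, and the region with the largest rise is drawn. That group means were higher in the Tg197 or TNF-treated cells in all 16 cases was therefore fixed by this choice. The rise ran from 1.46-fold for Nfkbie at 8 weeks to 1.98-fold for Tnip1 at 11 weeks. Both 8 week comparisons share their WT libraries.

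The comparison of TNF-treated with untreated WT cells at 8 weeks addressed the response to added TNF, whose dose and duration are not given in the sources used here. Nfkbia rose from 453.4 ± 12.1 to 856.5 ± 100.1 normalized reads (chromosome 12, 56590201 to 56593100), 1.89-fold and the largest rise among named promoters (log2 change 0.91 ± 0.14, limma adjusted p = 0.046). Tnfaip3 rose from 495.7 ± 45.9 to 908.4 ± 137.4 and Sod2, the mitochondrial superoxide dismutase, from 254.1 ± 15.1 to 465.1 ± 30.6, each 1.83-fold. Ch25h rose 1.85-fold and Jak2, a kinase of cytokine receptors, 1.82-fold. Ifi204, an interferon-inducible DNA sensor of the same gene family as Mndal, rose 1.78-fold. Comp, a cartilage matrix protein gene, fell from 395.9 ± 26.3 to 230.9 ± 48.4 (log2 change -0.80 ± 0.17), Csf1, the macrophage growth factor gene, from 266.5 ± 17.5 to 167.3 ± 23.7, and Sp7 by 0.86 on the log2 scale. The largest decreases among named promoters were at Hrh3, a histamine receptor gene (47.2 ± 27.1 against 168.7 ± 68.6, log2 change -1.90 ± 0.63), Kirrel2 (-1.81 ± 0.58), Wfdc3 (-1.60 ± 0.46), Sec14l3 (-1.59 ± 0.40) and the chemokine receptor gene Ccr7 (-1.53 ± 0.51).

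The NF-kB list had 11 members higher (Birc3, Cyld, Icam1, Map3k8, Nfkb2, Nfkbia, Nfkbie, Ripk2, Sod2, Tnfaip3 and Tnip1) and Rela lower. It passed the direction test (adjusted Fisher's exact p = 0.0256) and the presence test (adjusted Fisher's exact p = 1.12e-08). The presence test was again against genes with or without the mark. Random lists of listed promoters of similar level had a median log2 change of 0.42, so much of the rise was common to such promoters. In limma 12 members passed over all regions and 12 adjusted over the list alone, and the median log2 change of 0.64 was 1.14 and 0.53 under the other scalings. The kinase gene Ripk2, which signals from NOD receptors, rose from 420.9 ± 27.9 to 663.4 ± 99.0 and Birc3 from 311.7 ± 45.9 to 484.7 ± 22.3.

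Extracellular matrix genes Col12a1, Fmod, Loxl1 and Thbs1 were lower with TNF and none was higher, 3 past limma over all regions and 4 adjusted over the list alone. The list's adjusted Fisher's exact p for direction was 0.758, and its median log2 change of -0.81 stayed negative under both other scalings (-0.31 and -0.92). The aggrecanase genes Adamts1 (1.36-fold) and Adamts5 (1.33-fold) rose, and Timp3, an inhibitor of such enzymes (-0.43 ± 0.16), and Mmp11 fell. The osteoblast gene Sp7 and the Wnt receptor gene Fzd1 were lower in the bone and Wnt/BMP list. Cell cycle had Trp53 higher and Ccnb1, Cdkn1a and Mki67 lower, and the homeobox list had Msx1 higher and Hoxa10, Hoxa13, Hoxa9 and Hoxd13 lower, with medians of -0.44 and -0.35 on the log2 scale that turned to 0.07 and 0.15 with scaling to the listed regions. In limma 2 cell cycle members and 1 homeobox member passed over all regions, and 0 of either adjusted over the list alone. The fall of Hoxa13 rested on 1 WT library (limma adjusted p = 0.402). Cytoskeleton and adhesion had Itgav (1.52-fold) and Ptk2 (1.46-fold) higher and Myl9, Rock2 and Vcl lower, with a median of -0.51 that went to 0.00 with scaling to the listed regions, and the medians of interferon response (-0.02 to 0.49) and protease genes (-0.01 to 0.50) turned with it. Irf1 rose 1.49-fold and Irf7 was lower, H2-K1 rose 1.39-fold, and Pdpn rose 1.51-fold while Pdgfrb was lower. Cebpa, Comp and Sox9, markers of fat and cartilage cells, fell, and leukocyte, endothelial, muscle, and nerve sheath and epithelial markers had no member.

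The TNF table had 2985 regions past the authors' adjusted p, 757 higher and 2228 lower (25.4% higher, 95% interval 23.8 to 27.0). Higher regions lay within 3 kb of a TSS in 93.9% of cases and lower ones in 46.9% (odds ratio 17.5, Fisher's exact p = 5.78e-136). By limma 509 regions rose and 1314 fell (1823 in all). The counts were 772 and 259 with scaling to the listed regions and 221 and 1946 with scaling to regions within 1 kb of a TSS. Limma called 0 regions without TNF library b or c or WT library a or b, and 2770 without WT library c, while voom called 1984 with all 6 libraries.

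**Figure D4:**
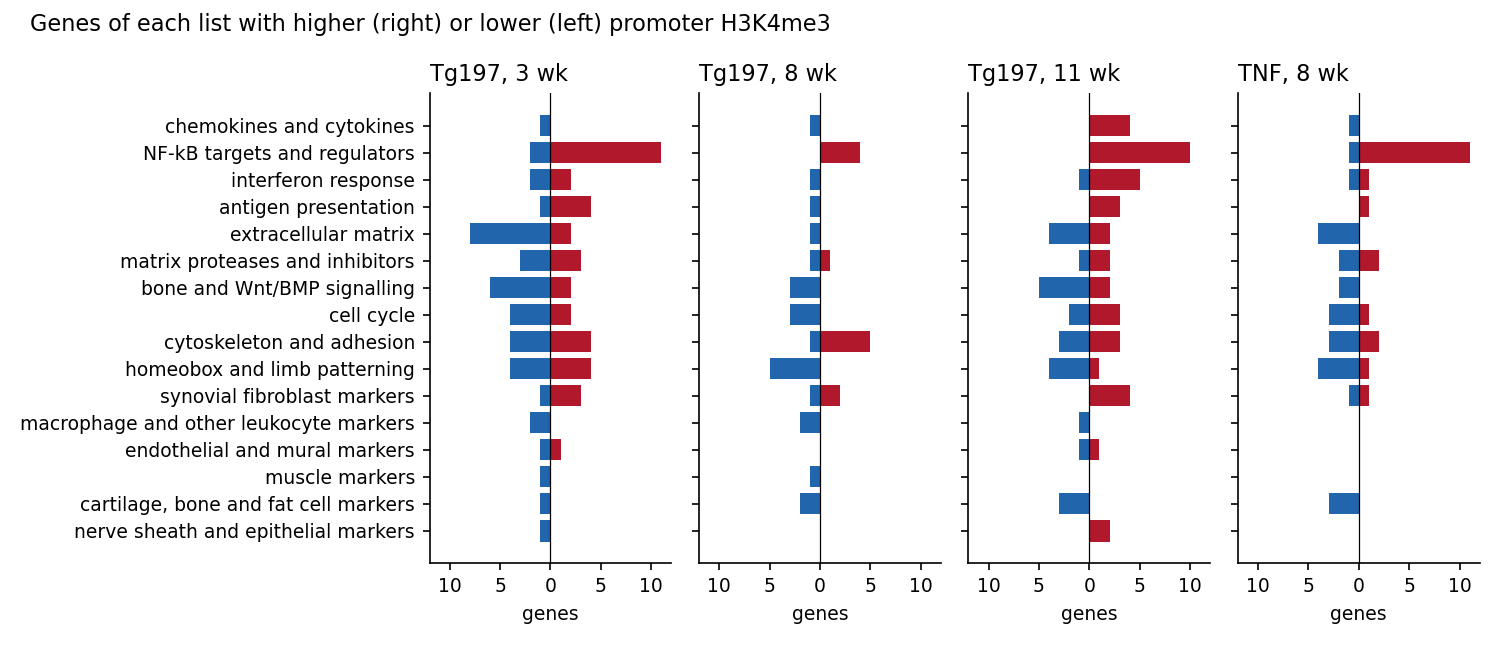
Number of genes (x axis) of each of the 16 lists (y axis) with higher (bars to the right) or lower (bars to the left) promoter H3K4me3 in the 4 comparisons, past the authors' adjusted p of 0.05 and with directions as in the authors' scaling, under which the median change of several lists turns when libraries are scaled to the listed regions. The NF-kB list had 11, 4, 10 and 11 genes higher and 2, 0, 0 and 1 lower.

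The 3 ages were compared through genes with promoter regions, matched by name, and through regions that overlapped between tables, since scaling and listed regions differ from table to table. Regions of a gene matched by name need not overlap. Promoter regions were higher at all 3 ages for 21 genes, 19 of them protein-coding where 0.65 would be shared by independent lists, and lower at all 3 ages for 14 genes, 12 of them protein-coding where 1.03 would be shared. Independent lists drew on all protein-coding genes, with or without the mark, so these expected numbers are low. The higher ones included Tnfaip3, Nfkbia, Nfkbie, Tnip1, Ccnd1, the death receptor gene Fas and Yap1, a regulator of the Hippo pathway. Genes with promoter regions in both directions were counted in both, and Ccnd1 also had a lower promoter region at 3 and 8 weeks. The lower ones included Sp7, Comp, the limb patterning gene Hoxa13, Tgfb2, the cytokinesis gene Racgap1, the SUMO ligase gene Pias4, Clec11a, which encodes a bone growth factor, and Ppfia1. Sp7 had log2 changes of -0.74 ± 0.19, -1.06 ± 0.31 and -0.68 ± 0.14 at 3, 8 and 11 weeks, although its 3 week region did not overlap those of 8 and 11 weeks.

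Between 3 and 8 weeks 394 pairs of changed regions overlapped, 88.6% of them in the same direction (95% interval 85.0 to 91.5) where the directions of both tables alone give 73.5%. Between 3 and 11 weeks 719 pairs overlapped, with 78.9% in the same direction (75.7 to 81.8) against 65.4%. Between 8 and 11 weeks 205 pairs did, with 73.2% (66.6 to 79.1) against 61.2%. These expected shares take no account of position relative to a TSS, which went with direction in each table. Of pairs with both regions in promoters 77.7%, 78.1% and 71.4% went in the same direction, and no expected share was computed for them. Circular shifts gave means of 46.0, 112.2 and 19.6 pairs, and the p of 0.001 in each case was the smallest that 1000 shifts can give in this permutation test. Shifts ignore that places with too few reads to show a difference could not be listed. The 128 pairs lower at 3 and higher at 11 weeks alone exceeded the mean of 112.2, so this p does not show a shared response. Genes with a higher promoter region were shared by 3 and 11 weeks in 125 cases (32.1 from independent lists) and genes with a lower one also in 125 (45.0 from independent lists). Opposite directions were shared more often than by independent lists in 78 genes lower at 3 and higher at 11 weeks (44.3, odds ratio 1.91), but not clearly in the 39 higher at 3 and lower at 11 weeks (32.6, adjusted Fisher's exact p = 0.27). They were also shared more often in 31 higher at 8 and lower at 11 weeks (14.3, odds ratio 2.32) and 29 lower at 8 and higher at 11 weeks (15.8, odds ratio 1.93). Between 3 and 8 weeks same directions were shared by 65 higher (20.8) and 117 lower genes (32.3), and opposite ones by 41 (23.4) and 49 (28.7). Of 263 pairs of promoter regions that overlapped by at least 50% of each, 39 went in opposite directions at the 2 ages.

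At 8 weeks Tg197 and TNF-treated cells were both compared with the same 3 WT libraries, which by itself makes their changes alike. They had 416 overlapping pairs of changed regions, against a mean of 12.2 over shifts, and 94.5% went in the same direction (95% interval 91.8 to 96.5) where 64.4% would by the directions alone. Genes with a higher promoter region in both numbered 100 (12.5 from independent lists, odds ratio 11.7, adjusted Fisher's exact p = 3.5e-60), and with a lower one 141 (19.5, odds ratio 11.4, adjusted Fisher's exact p = 1.58e-80), while opposite directions were shared by 25 (17.3) and 12 (14.1). None of these expected values allows for the shared WT libraries. The expected share also takes no account of position, and the expected numbers of pairs and genes take no account of which places carry signal. In data simulated with shared controls and no change, 108.8 of 6005 regions passed an unadjusted p of 0.05 in both comparisons, against 16.8 with separate controls, and 100.0% of them had the same sign, so the share in the same direction does not separate a common response from the common controls. With 3 control libraries the controls could not be divided between both comparisons.

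Overlaps with separate WT libraries were tested after seeing the data. Between 3 week Tg197 and TNF treatment there were 509 pairs, 88.8% in the same direction (85.7 to 91.4) against 69.8% by direction alone. Between 11 weeks and TNF there were 240 pairs, 75.4% (69.5 to 80.7) against 59.5%. The expected shares again take no account of position. Of pairs with both regions in promoters 81.0% and 73.6% went in the same direction, with no expected share computed. Genes with a higher promoter region in both the 3 week and the TNF comparison numbered 125 (28.7 from independent lists, odds ratio 5.79), and 73 in both the 11 week and the TNF comparison (19.4, odds ratio 4.51). The numbers from independent lists are low here too, since they drew on all protein-coding genes. Opposite directions were shared more often than by independent lists in 2 of 4 cases, by 65 genes higher at 3 weeks and lower with TNF (39.7, odds ratio 1.74) and 58 higher at 11 weeks and lower with TNF (26.8, odds ratio 2.37), and not by the 44 lower at 3 weeks and higher with TNF (39.6, adjusted Fisher's exact p = 0.494) or the 19 lower at 11 weeks and higher with TNF (19.7).

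In all 4 comparisons, of which 2 share their WT libraries, 11 genes had a higher promoter region (10 protein-coding), namely Nfkbia, Nfkbie, Tnfaip3, Tnip1, Fas, Hivep2, Yap1, Ninl, Osbpl5, Sbno2 and 6330406I15Rik. A lower promoter region was found in all 4 for 8 genes (7 protein-coding), namely Comp, Sp7, Tgfb2, Hoxa13, Evx2, Dhrs3, Pias4 and Rn4.5s. With TNF 1 WT library carried the fall of Hoxa13 (WT 132.1, 318.2 and 149.3, TNF 164.6, 153.6 and 139.2, limma adjusted p = 0.402). Limma also did not pass Fas (adjusted p = 0.12), Yap1 (0.0862), Dhrs3 (0.0831) and Rn4.5s (0.0872) at 3 weeks. Nor did it pass Rn4.5s with TNF (0.0572) or any region at 8 weeks. Genes were matched by name. For each of the 8 lower genes the regions with the largest falls did not all overlap between comparisons, and those of Rn4.5s all lay apart. Among the higher genes the regions with the largest rises did not all overlap for Fas, Osbpl5 and 6330406I15Rik.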

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

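In this part, the tests of depth, background, a mislabelled library and counting error were chosen after the results they bear on had been seen. The splits of the libraries were planned, and the test between ages was not among the tests fixed before the data were examined.

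In 31 of 263 pairs of promoter regions that overlapped by at least 50% of each the Tg197 effect went opposite ways at 2 ages with no overlap between Tg197 and WT values at either age, and the 6 genes with the largest differences are given. Myo1g, a myosin of haematopoietic cells, was lower at 8 weeks (log2 change -1.29) and higher at 11 weeks (0.59), a difference of -1.88. Nat14, a predicted acetyltransferase gene, was lower at 8 weeks (-0.94) and higher at 11 weeks (0.60), a difference of -1.54. Cd244, a receptor of natural killer cells, was lower at 3 weeks (-0.84) and higher at 11 weeks (0.73), a difference of -1.57. Arhgap9 (-0.81 and 0.75, difference -1.56) and Tnfrsf18, which encodes the TNF receptor family member GITR (-0.86 and 0.60, difference -1.46), did the same. Rab3ip, a gene of vesicle transport, was higher at 3 weeks (0.61) and lower at 11 weeks (-0.88), a difference of 1.49. Each permutation p was 0.005, the smallest that 400 permutations can give (0.0424 adjusted), but any pair of this kind gets that value and the regions had been selected for a difference at each age, so it does not show that the ages differ. The regions overlapped without being identical, and these differences were not tested under the other scalings.

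The main pattern was lower H3K4me3 away from promoters in Tg197 and TNF-treated cells, at -0.72, -0.99, -0.65 and -1.21 on the log2 scale. The slope of level on scaled depth within groups predicted at most 38.9% of the fall in the 4 tables (45.4% at most when any group was left out). Depth and level were strongly related within groups (Pearson r = -0.88, permutation p = 0.00021), but depth is the inverse of the factor that scales the level. The regions had also been selected for a fall between these groups, which enlarges the fall and favours a low spread within groups. The share of the fall due to depth can therefore not be told from this slope. At 11 weeks the groups differed by 0.08 in log2 depth and by -0.65 in level. Less background relative to signal is a candidate explanation. Across 21 libraries, within their groups, libraries lower at these regions were higher at promoters (Pearson r = -0.64, permutation p = 0.0028). Both sets of regions had been selected for a difference between the groups. An effect of the transgene or of TNF that varied between libraries would give the same sign, so this correlation does not single out background. At most 0.04% of 10000 random promoter lists matched on level had a median as high as the NF-kB list. Random medians were 0.35, 0.44, 0.31 and 0.42 against 0.47, 0.73, 0.72 and 0.64, so much of the rise was common to listed promoters of that level. The random lists were matched on mean normalized reads, not on enrichment over input or region length. Background as the source of the NF-kB result can therefore not be told apart from a change particular to the list. An effect of the transgene or of TNF on these regions stays open and was not tested apart from background.

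WT library c at 8 weeks lay 74.8% of the way from the other WT libraries to the Tg197 mean at lower regions away from promoters, and 57.2% of the way to the TNF-treated mean. At higher promoters it lay 15.3% and 20.5% of the way, but those regions had been selected with this library among the WT ones, so a mislabelled library cannot be told apart from a variable WT library. The scaled depth of this library, 2.11 times that of the others, predicted 47.5% of its fall (45.7 to 49.1 with other groups left out). The slope has the limits given above and the rule for reading this share was set after the results were seen. How much of the fall is due to depth can therefore not be told. No biological explanation was tested.

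The smallest adjusted p in the authors' deposited table fell on regions with small folds at 8 weeks (55 regions at 9.52e-08, median absolute log2 change 0.37 against 0.93 elsewhere). The 11 week and TNF tables had the same pattern (0.38 against 0.64, and 0.31 against 0.63), and the 3 week table did not (0.90 against 0.68). The median chi-square per degree of freedom within groups at these regions was at most 0.71 in the 3 tables with small folds, against 0.84 from counting error alone, but a small p at a small fold needs a low spread, so libraries that differ by less than counting error cannot be told apart from the choice of regions by their p. A share of 43.6%, 37.8% and 45.9% of them at 8 weeks, 11 weeks and with TNF had a counting p over 0.0001. No biological explanation was tested.

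The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. Limma called 12733 regions in the real split at 3 weeks and at most 2 in another (1 split with as many), 6414 and at most 2 at 11 weeks (1 split), and 1823 and at most 238 in the TNF table (1 split). At 8 weeks it called 0 in the real split (1876 at an unadjusted p under 0.05, voom 0) and up to 306 in another, so all 10 splits gave as many.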

How the results depend on the processing

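The 2 other scalings and voom were chosen after seeing the data. Of 156 alternatives, 106 left the result the same by the rule for that result, 3 reversed it and 47 moved it or took it past or short of its threshold. For odds ratios of position the rule asked only for the same direction and a Fisher's exact p under 0.05. Values are given in the order 3, 8 and 11 weeks and TNF. Odds ratios for position near a TSS stayed above 1 but moved in size, from 55.0, 20.2, 3.1 and 17.5 within 3 kb to 107, 8.6, 4.71 and 8.81 within 1 kb, and to 55.9, 24.4, 3.61 and 8.76 within 3 kb at an adjusted p under 0.001. Below, where no reason is given the cause was not tested.

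Fewer regions pass stricter rules by construction. An absolute log2 change of at least 1 left 594, 1244, 121 and 1037 regions, with 0.0%, 0.5%, 11.6% and 0.0% higher. Promoter regions alone numbered 2957, 1127, 1663 and 1755, with 40.3%, 46.1%, 49.7% and 40.5% higher. An adjusted p under 0.001 left 1554, 3676 and 1324 regions at 8 weeks, 11 weeks and with TNF, and 9.1% higher at 3 weeks.

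With each library scaled to its median over the listed regions limma called 946, 414, 2759 and 1031 regions. The share that rose was 99.4%, 75.3% and 74.9% at 3 weeks, 11 weeks and with TNF, reversed from 5.0%, 30.4% and 27.9%, since most listed regions were lower and this scaling moves their median toward no change. With scaling to listed regions within 1 kb of a TSS limma called 12241, 1730, 6005 and 2167 regions, of which 3, 12, 1486 and 221 rose (10.2% with TNF). More regions near a TSS were higher than lower, so this scaling moves promoters down by construction.

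Leaving out 1 library gave 0 to 13397 regions past limma at 3 weeks (0 without WT library c, 9776 at an unadjusted p under 0.05), 0 to 2563 at 8 weeks (2563 without WT library c), 6139 to 6276 at 11 weeks and 0 to 2770 with TNF. With TNF it was 2770 without WT library c, and 0 without TNF library b or c or WT library a or b (1125, 1187, 1139 and 1234 at an unadjusted p under 0.05). Voom was not run on these subsets.

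The number of gene lists past the direction test became 1 (the NF-kB list) at 3 weeks at an adjusted p under 0.001. At 11 weeks it was 1 (the NF-kB list), and became 2 with regions of any class, where the chemokine and cytokine list also passed. It was 0 at an adjusted p under 0.001 and 0 with every listed region.

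Overlapping pairs between ages went from 1318 to 674 when 50% of each region had to be shared, 573 at an adjusted p under 0.001 and 787 as shared genes, and the same-direction share from 80.9% to 84.0% with that rule and 66.1% as genes. For Tg197 and TNF at 8 weeks 416 pairs became 94 at an adjusted p under 0.001, with 91.5% in the same direction, and 86.7% as genes.

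No paired analysis was possible because the values carry no replicate numbers, and for the same reason no replicate block was fitted. The edgeR quasi-likelihood test, DESeq2 and a low-count filter, planned for deposited counts, were not run on the recovered reads. In the simulated data 2-fold changes were recovered in 93%, 32%, 100% and 89% of regions, rates that do not carry over to the real tables. The effect of depth apart from spread was not tested.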

Other observations

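The genes and counts in this part were chosen after seeing the data, and no explanation was tested.

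Inhba, which encodes a subunit of activin A, had a gene-body region with more H3K4me3 in 3 comparisons. It rose from 117.5 ± 7.8 to 171.5 ± 37.3 normalized reads at 3 weeks (1.46-fold, n = 3, limma adjusted p = 0.0214) and from 354.7 ± 17.4 to 474.6 ± 26.6 with TNF (1.34-fold, limma adjusted p = 0.046). At 8 weeks it was 266.6 ± 42.1 against 171.1 ± 12.8 (1.56-fold, limma adjusted p = 0.0725), and no region of it was listed as higher at 11 weeks.

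At 11 weeks 720 gene-body regions over 654 genes were higher in Tg197, against 59, 43 and 23 at 3 weeks, 8 weeks and with TNF. They lay at a median of 18128 bp from the TSS, 31.5% of them within 10 kb, and had a median of 81.8 normalized reads in WT. Ntn1, a guidance factor, had 4 of them (1.82, 1.51, 1.61 and 1.9-fold). The receptor kinase gene Axl had 2 (132.5 ± 12.8 against 80.0 ± 4.5, and 226.1 ± 21.9 against 166.1 ± 7.2) and a promoter region 1.42-fold higher. The neutrophil chemokine gene Cxcl5 had 1 (215.9 ± 36.8 against 132.4 ± 11.5).

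Lower gene-body regions at 3 weeks numbered 6256 over 3001 genes, the most in Dnahc8 (40), followed by 33 in Gm13152, 23 in Btbd9, 23 in Smg6 and 21 in Rere. Chromosome 11 held 19.2% of lower regions at 3 weeks (7.3% of higher ones), 10.2% at 8 weeks (9.2%), 12.8% at 11 weeks (12.8%) and 18.7% with TNF (4.9%), and makes up 4.6% of the span of the listed regions at 3 weeks. Chromosome X held 0.6% of lower regions at 3 weeks and makes up 6.3% of that length.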
